A study of Mus musculus with 4 samples.

How the data were processed

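The data were the deposited gene-by-barcode matrices of 4 spleen libraries, 2 WT and 2 D3TA, 1 per mouse, grouped by the labels. The values are counts of unique molecular identifiers (UMIs), not normalized, made by the authors with Cell Ranger 7.0.1 per the file headers, against mm10 per the submitters' processing notes. Whether intronic reads were counted, which end of the transcript was sequenced and which annotation release was used are not given in the sources used here. Per the labels' protocols, spleens were dissociated with scalpel and needle and filtered, red cells were lysed, and libraries were made on a Chromium X with GEM-X chips for a target of 10000 cells per sample. The deposited counts covered 32285 genes, 78 of which share their symbol with another, and 64410 barcodes.

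Cells were kept with at least 500 UMIs, at least 250 genes and at most 10% mitochondrial UMIs, which left 53945. Scrublet scores from scanpy 1.11.5, at an expected doublet rate of 6%, marked 3.03%, 5.88% and 3.6% of WT replicate 2, D3TA replicate 1 and D3TA replicate 2. Its automatic threshold marked 0 cells of WT replicate 1, so the mean threshold of the other 3 libraries was used there, a choice made after the data were seen, which marked 2.23%. Without these 1873 doublets, 52072 cells were analysed. Counts were scaled to 10000 per cell, 2000 variable genes were ranked jointly over libraries without sex-linked, mitochondrial, ribosomal, hemoglobin and receptor genes, and 30 principal components, 15 neighbours and Leiden clustering at resolution 1 gave 44 clusters with no batch integration. A cluster took the class whose markers scored highest, from 17 classes with 193 markers of which 2 were not among the genes. These markers, the gene lists, the named-gene rule and the main tests were fixed before the data were examined. At least 3 markers had to be detected and the leading genes could not go against the name. Rules added after the data were seen left a cluster unnamed where 4 or more of its 10 leading genes were immunoglobulin genes outside B and plasma cells, or where it shared 5 or more with a better separated cluster of another class. 13 classes were named and 6 clusters stayed unnamed.

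UMIs were summed per library and class and tested with edgeR 4.0.16 (filterByExpr, TMM factors, quasi-likelihood test, Benjamini-Hochberg adjustment, two-sided, adjusted p under 0.05), with DESeq2 1.42.0 as an alternative. Cell counts per class were tested by edgeR's quasi-likelihood test without TMM factors. The 25 gene lists were compared with limma 3.58.1 by camera (preset correlation 0.01), and again with an estimated correlation and with fry, which tests whether a list moves one way and does not compare it with other genes. Over 6 fits, camera called 85 lists, 0 of them with an estimated correlation, and fry called 4. Genes were named if called, moved the same way in every D3TA against every WT library and had a mean of at least 20 CPM, with 12 per direction in the whole spleen and neutrophil-like cells and 8 in other classes. Immunoglobulin and T cell receptor segments and unnamed gene models were left out, and within classes so were genes under 1 part in 5 of their level in their highest class, for which RNA free in the droplets was held possible. The level in the class was a mean over all libraries, so passing this limit does not clear a gene of free RNA in a single group. The 4 members with the smallest p of each list called, and Ccnd1, Ccnd2, Ccnd3, Cdk4 and Cdk6, were named too. Intervals of shares are exact (Clopper-Pearson, 95%), and the floor of a count of 0 is 3 UMIs over the group. Positions come from GENCODE's GRCm38 annotation, not shown to be the release the authors used.

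Each fit was tested on simulated counts with 200 changed genes. edgeR recovered 64% of 4-fold and 19% of 2-fold changes among 18333 whole-spleen genes, 55% and 6% among 12896 genes of neutrophil-like cells, and 79% and 9% among 10644 genes of monocyte- and macrophage-like cells, and 1.61% to 5.83% of calls were false over the 7 fits. Alternatives covered all barcodes, a stricter filter (1000 UMIs, 500 genes, 5% mitochondrial), doublets kept, names from a marker score per cell, Leiden resolutions 0.5 and 2, median-ratio scaling, no filter on low counts, DESeq2, fits without genes of possible free RNA, a replicate block and each library left out. Unnamed clusters counted with their closest class, mature neutrophil-like cells alone and a crossed block were chosen after the data were seen. Reads were not used here, so the edited codon was not read. Values of some single genes are not reported here. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, leidenalg 0.10.2 and R 4.3.3 were used.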

Results

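Spleen cells of 4 female C57BL/6J mice were profiled by droplet single-cell RNA sequencing. Of these mice, 2 carried 1 copy of a knock-in allele of Ccnd3, the gene of the G1 cyclin D3, in which threonine 283 is replaced by alanine (D3TA), and 2 were wild type (WT). The mice were 12 and 16 months old, ages at which the knock-in animals show a myeloproliferative neoplasm, an overproduction of blood cells of the myeloid lineages. Each mouse gave 1 library, named here by its genotype and replicate number, and the labels do not say which mouse had which age. WT replicate 1 held 25829 cell barcodes and 83507825 unique molecular identifiers (UMIs, counted RNA molecules), and WT replicate 2 held 9888 barcodes and 81416981 UMIs. D3TA replicate 1 held 15294 barcodes and 143811696 UMIs, and D3TA replicate 2 held 13399 barcodes and 114430052 UMIs. Kept cells had a median of 1394 UMIs in WT replicate 1 against 8009, 8111 and 7698 in WT replicate 2, D3TA replicate 1 and D3TA replicate 2. With 2 mice against 2, an exact permutation test of a single value cannot go below p = 0.333. Differences were therefore tested with models that share their estimate of spread across cell classes or genes. Exact 95% intervals of shares cover counting error only.

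The first question was whether the transcript of the edited gene itself differed. Ccnd3 lies at chromosome 17, 47505051 to 47599691, on the plus strand of GRCm38. Codon 283, ACT in the reference, occupies positions 47598744 to 47598746 in the last exon of the 5 annotated transcripts that encode the 292-residue protein. A single substituted codon is not visible in counts per gene, so the level of Ccnd3 does not check the genotype labels. Over the whole spleen Ccnd3 stood at 466 ± 40.7 TMM-scaled CPM (SD, n = 2) in WT and 416 ± 41.2 in D3TA libraries. Its log2 fold change was -0.17 ± 0.21 (SE) with an edgeR adjusted p of 0.676. By unscaled CPM, T-cell-like cells held the highest levels among the named classes measured in both groups, at 951 ± 85.8 in WT and 923 ± 252 in D3TA libraries. Along the neutrophil lineage of the D3TA libraries, Ccnd3 was at 103 ± 11.9 CPM in precursor-like, 283 ± 9.89 in immature and 588 ± 11.4 in mature neutrophil-like cells. WT mature neutrophil-like cells held 879 ± 227 CPM, and WT cells of the earlier stages were too few for a mean. In edgeR fits within classes, the log2 fold change of Ccnd3 was -0.89 ± 0.37 in neutrophil-like cells of all stages (adjusted p = 0.141). It was -0.05 ± 0.45 in mature neutrophil-like cells (adjusted p = 0.956) and -0.18 ± 0.27 in monocyte- and macrophage-like cells (adjusted p = 0.73). Ccnd3 passed in neutrophil-like cells without WT replicate 1 (edgeR adjusted p = 0.0284). DESeq2 gave Ccnd3 a log2 fold change of -0.92 in these cells (adjusted p = 0.046).

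The second comparison asked how the cell types of the spleen differed between genotypes. Neutrophil-lineage cells, the precursor-like, immature and mature neutrophil-like cells together, made up 3.72% ± 2.33 (SD, n = 2) of WT and 27.3% ± 8.32 of D3TA spleen cells. The share was 5.37% (5.07 to 5.67) in WT replicate 1, 2.07% (1.76 to 2.41) in WT replicate 2, 33.1% (32.3 to 34.01) in D3TA replicate 1 and 21.4% (20.6 to 22.2) in D3TA replicate 2. B-cell-like cells made up 61.3% ± 10.1 of WT and 22.4% ± 23.01 of D3TA cells, with 54.1%, 68.4%, 6.09% and 38.6% in the same order of libraries. Unnamed cluster 9, closest to B cells, held 0.0226%, 0.0655%, 12.7% and 0.0947%, and counted with it and other clusters of that closest class the B-cell-like share of D3TA replicate 1 was 19.7%, with a log2 change of -1.11. T-cell-like cells made up 20.05% ± 5.61 of WT and 15.2% ± 6.64 of D3TA cells, and natural killer (NK) cell-like cells 1.04% ± 0.514 of WT and 0.283% ± 0.364 of D3TA cells. Cluster 2, with a median of 1178 UMIs per cell and marker scores of 2.13 for T and 1.94 for B cells, gave 4131 of the 5311 T-cell-like cells of WT replicate 1. At Leiden resolution 0.5 that library held 5.33% T-cell-like cells, and the log2 change of the share turned from -0.40 to 0.53, neither called by edgeR. Unnamed cluster 4, closest to T cells, held 0.0452%, 0.93%, 16.2% and 0.805%. D3TA replicate 1 held 3 NK cell-like cells among 11765.

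Erythroid-like cells were at 2.23% ± 0.577 of WT and 3.3% ± 1.41 of D3TA cells. Macrophage-like cells made up 1.56% ± 0.444 of WT and 1.94% ± 0.865 of D3TA cells, and monocyte-like cells 1.04% ± 0.419 of WT and 1.7% ± 0.662 of D3TA cells. Dendritic cell-like cells were at 2.41% ± 0.207 of WT and 2.11% ± 1.12 of D3TA cells, and plasma cell-like cells at 2.51% ± 0.147 of WT and 1.96% ± 0.473 of D3TA cells. Plasmacytoid dendritic cell-like cells were at 0.281% ± 0.0824 of WT and 0.129% ± 0.0345 of D3TA cells, and basophil- or mast cell-like cells at 0.291% ± 0.375 of WT and 0.457% ± 0.244 of D3TA cells. Red cells had been lysed before loading, which can set the erythroid share. The 6 clusters that were left unnamed held 3.62% ± 1.1 of WT and 23.3% ± 20.1 of D3TA cells. Cluster 7 combined granule genes such as Ngp, Camp and Ltf with immunoglobulin genes and was kept out of the neutrophil lineage by a rule set after the data were seen. It held 0.176%, 0%, 7.65% and 7.2% of the libraries in the same order, and cluster 22, kept out likewise, held 2.4%, 0.105%, 0.119% and 0.114%. Over 12 classes, edgeR's quasi-likelihood test on cell counts called 0 at an adjusted p under 0.05 and 2 at an unadjusted p under 0.05, and no other tool was run on these counts. The neutrophil lineage had a log2 fold change of 2.87 ± 1.05 (edgeR adjusted p = 0.0988), with an exact permutation p = 0.333, and the unnamed clusters 2.69 ± 1.04 (edgeR adjusted p = 0.0988). NK cell-like cells had -1.87 ± 1.03 (edgeR adjusted p = 0.327), and B-cell-like cells -1.45 ± 1.0 (edgeR adjusted p = 0.474). Leaving out D3TA replicate 2 brought the neutrophil lineage (3.15, adjusted p = 0.0275), NK cell-like cells (-5.29, adjusted p = 0.0275) and B-cell-like cells (-3.33, adjusted p = 0.0488) past edgeR's threshold. With unnamed clusters counted with their closest class, an alternative added after the data were seen, the lineage passed too (3.19, adjusted p = 0.0356 by edgeR).

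**Figure D1:**
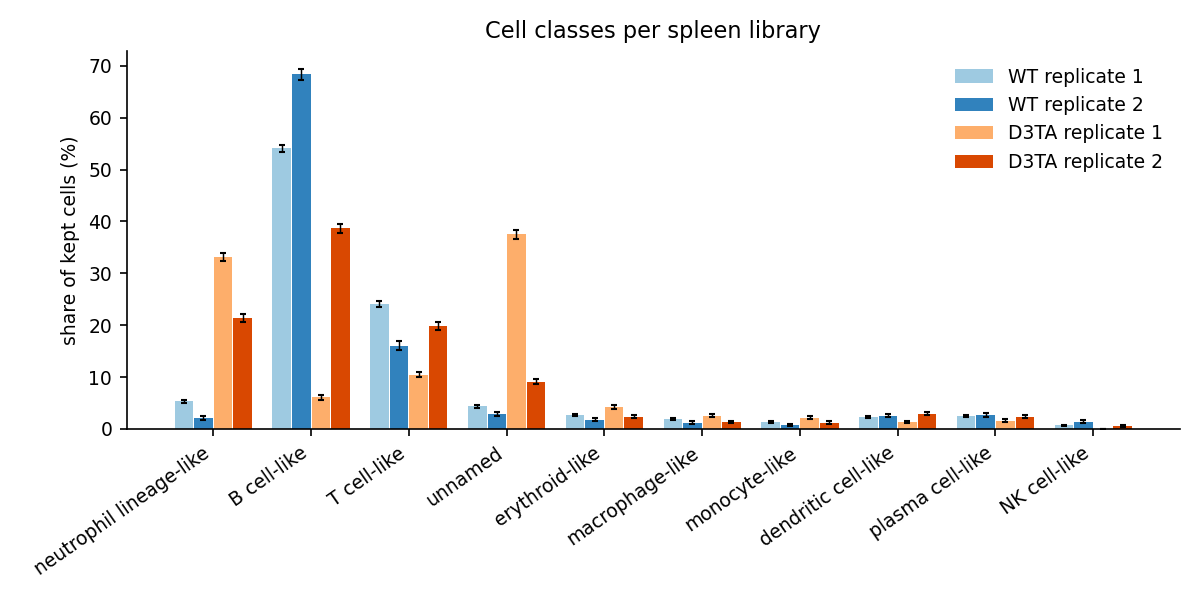
Share of kept cells (%, vertical axis) in 9 marker-named classes and in the unnamed clusters for each of the 4 spleen libraries; error bars are exact 95% binomial intervals and cover counting error only. Neutrophil-lineage cells stood at 5.37% and 2.07% in WT and at 33.1% and 21.4% in D3TA spleens.

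Within the neutrophil lineage, the comparison asked which maturation stages the cells had reached. Immature neutrophil-like cells, rich in the secondary granule genes Ltf, Camp and Ngp, made up 5.72% ± 7.13 (SD, n = 2) of the lineage in WT and 61.8% ± 6.53 in D3TA spleens. Their share was 0.674% of 1187 lineage cells in WT replicate 1 and 10.8% of 158 in WT replicate 2, against 57.2% of 3900 and 66.5% of 2257 in D3TA replicates 1 and 2. Mature neutrophil-like cells, marked by Cxcr2, Retnlg and Il1b, made up 92.3% ± 5.26 in WT and 33.5% ± 5.81 in D3TA spleens. Precursor-like cells with Elane, Mpo and Prtn3 made up 1.96% ± 1.88 and 4.62% ± 0.713, and all 39 of WT replicate 1 lay in cluster 42 against 198 of 200 and 92 of 93 of D3TA replicates 1 and 2 in cluster 33. The log2 fold change of the share was 3.58 ± 1.27 (edgeR adjusted p = 0.0648) for immature, -1.46 ± 0.76 (edgeR adjusted p = 0.136) for mature and 1.05 ± 0.90 (edgeR adjusted p = 0.28) for precursor-like cells, so no stage passed the threshold. Immature cells were higher and mature cells lower in both D3TA than in both WT libraries. Cluster 13, of low UMI counts, held 994 of 1140 mature cells in WT replicate 1. Cluster 10 held 116 of 140 in WT replicate 2 and 753 of 1468 and 350 of 664 in D3TA replicates 1 and 2. By edgeR, the immature share passed without WT replicate 2 (6.51, adjusted p = 0.0089), without D3TA replicate 1 (3.69, adjusted p = 0.0352) and without D3TA replicate 2 (3.48, adjusted p = 0.0481), and was 2.52 (adjusted p = 0.23) without WT replicate 1. It also passed under 5 planned settings of cell filter, doublets or naming, with edgeR adjusted p from 0.0178 to 0.0481.

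**Figure D2:**
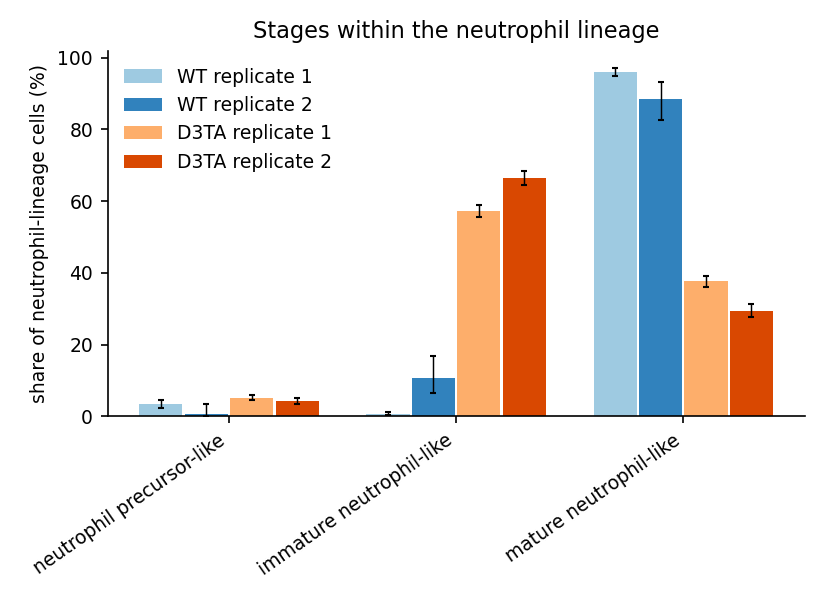
Share of neutrophil-lineage cells (%, vertical axis) at each of 3 stages in each library; error bars are exact 95% binomial intervals and cover counting error only. Immature cells stood at 0.674% and 10.8% in WT and at 57.2% and 66.5% in D3TA spleens.

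Summed over all cells of a spleen, genes of granule formation stood far above their WT level in the D3TA libraries. This comparison moves with the mix of cells as well as with expression within a cell. Elane (neutrophil elastase, chromosome 10, 79886247 to 79888215) rose from 6.17 ± 4.07 to 614 ± 296 CPM (SD, n = 2), a log2 fold change of 6.63 ± 0.72 (SE, edgeR adjusted p = 0.0133). The other azurophil granule enzymes Prtn3 (6.34 ± 0.72, adjusted p = 0.0148), Ctsg (6.32 ± 0.86, adjusted p = 0.0208) and myeloperoxidase, Mpo (6.27 ± 1.03, adjusted p = 0.0349), rose too. Ltf, the lactoferrin of secondary granules (chromosome 9, 111019271 to 111042767), rose from 33.1 ± 16.1 to 2303 ± 454 CPM (6.12 ± 0.51, edgeR adjusted p = 0.00858). The neutrophil surface genes Cd177 (6.02 ± 0.29, adjusted p = 0.00554) and Itgb2l (6.18 ± 0.42, adjusted p = 0.00659) and the transporter gene Abca13 (5.89 ± 0.34, adjusted p = 0.00554) rose likewise. So did the precursor marker Ms4a3 (6.01 ± 0.50, adjusted p = 0.00858) and Cebpe (5.92 ± 0.52, adjusted p = 0.00895), a transcription factor of late granulocyte differentiation. Inhba, a subunit of activins, rose from 0.546 ± 0.136 to 49.4 ± 8.76 CPM (6.50 ± 0.29, edgeR adjusted p = 0.00554). Prss34, a protease gene of basophils and mast cells, completed the 12 largest rises (7.29 ± 1.30, edgeR adjusted p = 0.0425). Basophil- or mast cell-like cells of WT replicate 1 held Prss34 at 10.5 CPM, the 2 such cells of WT replicate 2, with 4714 UMIs in all, at 9546 CPM, and those of D3TA replicates 1 and 2 at 16706 and 9823 CPM. edgeR called 1108 of 18333 genes, 1038 higher and 70 lower in D3TA spleens, and DESeq2 called 2439 (1851 higher, 588 lower). The libraries of the groups did not overlap in 57.5% of tested genes (33.3% by chance). The count was 333 (313 higher, 20 lower) without WT replicate 1, 259 (251 higher, 8 lower) without WT replicate 2 and 5423 (3214 higher, 2209 lower) without D3TA replicate 2, and 1310 (1096 higher, 214 lower) without D3TA replicate 1. Prss34 and Mpo missed the threshold without D3TA replicate 1 (edgeR adjusted p = 0.0681 and 0.0642).

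The 12 largest falls in the whole spleen included genes of the B cell receptor. Vpreb3, a surrogate light chain gene, had a log2 fold change of -1.84 ± 0.33 (SE, edgeR adjusted p = 0.0445). Cd79a (-1.17 ± 0.22, adjusted p = 0.0484) and Cd79b (-1.14 ± 0.21, adjusted p = 0.0465), the signalling chains of the B cell receptor, and Fcmr (-1.18 ± 0.22, adjusted p = 0.0485), the receptor of IgM, fell as well. Id3 (-1.30 ± 0.21, adjusted p = 0.0323), an inhibitor of helix-loop-helix transcription factors, fell, and Bfsp2, Pdzd2, Dmac2, Haao, BE692007, Filip1l and Chchd10 had log2 fold changes between -1.14 and -1.42. B-cell-like cells made up fewer of the cells in both D3TA than in both WT spleens (6.09% and 38.6% against 54.1% and 68.4%). None of these 12 falls passed edgeR without WT replicate 1, with adjusted p from 0.0973 for Pdzd2 to 0.457 for Cd79b. None passed without WT replicate 2 either, from 0.0706 for Vpreb3 to 0.433 for Cd79a. Vpreb3, Id3, Pdzd2 and Chchd10 also missed the threshold without D3TA replicate 1 (edgeR adjusted p = 0.0517, 0.0645, 0.0917 and 0.0513).

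The fixed gene lists were then compared with all other genes of the whole spleen by limma's camera test (preset correlation of 0.01). A gene passed within its list where its p, adjusted over the genes of that list alone, was under 0.05. Of 9 primary granule genes, 7 rose, such as Fcnb (5.70 ± 0.48) and Prss57 (5.42 ± 0.55), and 7 passed within the list (median log2 fold change 6.01, camera adjusted p = 1.48e-06, against 0.408 with an estimated correlation). Of 19 secondary and tertiary granule genes, 17 rose, such as Wfdc21 (5.64 ± 0.32) and the collagenase gene Mmp8 (4.81 ± 0.37), and 18 passed within the list (median log2 fold change 4.89, camera adjusted p = 3.74e-16, against 0.408 with an estimated correlation). Of 23 mature neutrophil genes, 11 rose, such as the formyl peptide receptor gene Fpr2 (4.57 ± 0.27), the calprotectin genes S100a8 (5.44 ± 0.51) and S100a9 (5.37 ± 0.59), and 20 passed within the list (median log2 fold change 2.68, camera adjusted p = 6.65e-11, against 0.408 with an estimated correlation). Of 43 S phase genes, 22 rose, such as E2f8 (2.64 ± 0.27) and the replication factor gene Cdc45 (2.10 ± 0.23), and 36 passed within the list (median log2 fold change 1.18, camera adjusted p = 1.73e-15, against 0.408 with an estimated correlation). Of 51 G2/M phase genes, 41 rose, such as the mitotic kinesin genes Kif2c (2.30 ± 0.23) and Kif11 (2.0 ± 0.17), and 50 passed within the list (median log2 fold change 1.84, camera adjusted p = 2.47e-23, against 0.408 with an estimated correlation). Of 26 cyclin D, CDK and RB pathway genes, 4 rose, namely Cdk2 (1.19 ± 0.16), Ccne2 (1.79 ± 0.27), E2f1 (1.60 ± 0.24) and the CDK inhibitor gene Cdkn2c (1.69 ± 0.31), and 9 passed within the list (median log2 fold change 0.53, camera adjusted p = 0.00443, against 0.408 with an estimated correlation). Ccnd1 (-0.60 ± 0.19, edgeR adjusted p = 0.151), Ccnd2 (-0.03 ± 0.16, 0.932), Cdk4 (0.50 ± 0.21, 0.254) and Cdk6 (0.55 ± 0.17, 0.15) did not pass. Ccnd1 and Cdk4 passed in the whole spleen without D3TA replicate 2 (edgeR adjusted p = 0.0267 and 0.0144). Cdc45, Kif11, Cdk2, Ccne2, E2f1, Cdkn2c, S100a8 and S100a9 missed the threshold without WT replicate 1 (edgeR adjusted p = 0.0593, 0.0713, 0.224, 0.13, 0.175, 0.191, 0.0565 and 0.0736). The same genes also missed it without WT replicate 2 (edgeR adjusted p = 0.0643, 0.0584, 0.227, 0.0644, 0.101, 0.105, 0.0749 and 0.0909). Ccne2, E2f1 and Cdkn2c missed the threshold without D3TA replicate 1 (edgeR adjusted p = 0.061, 0.0517 and 0.0633).

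**Figure D3:**
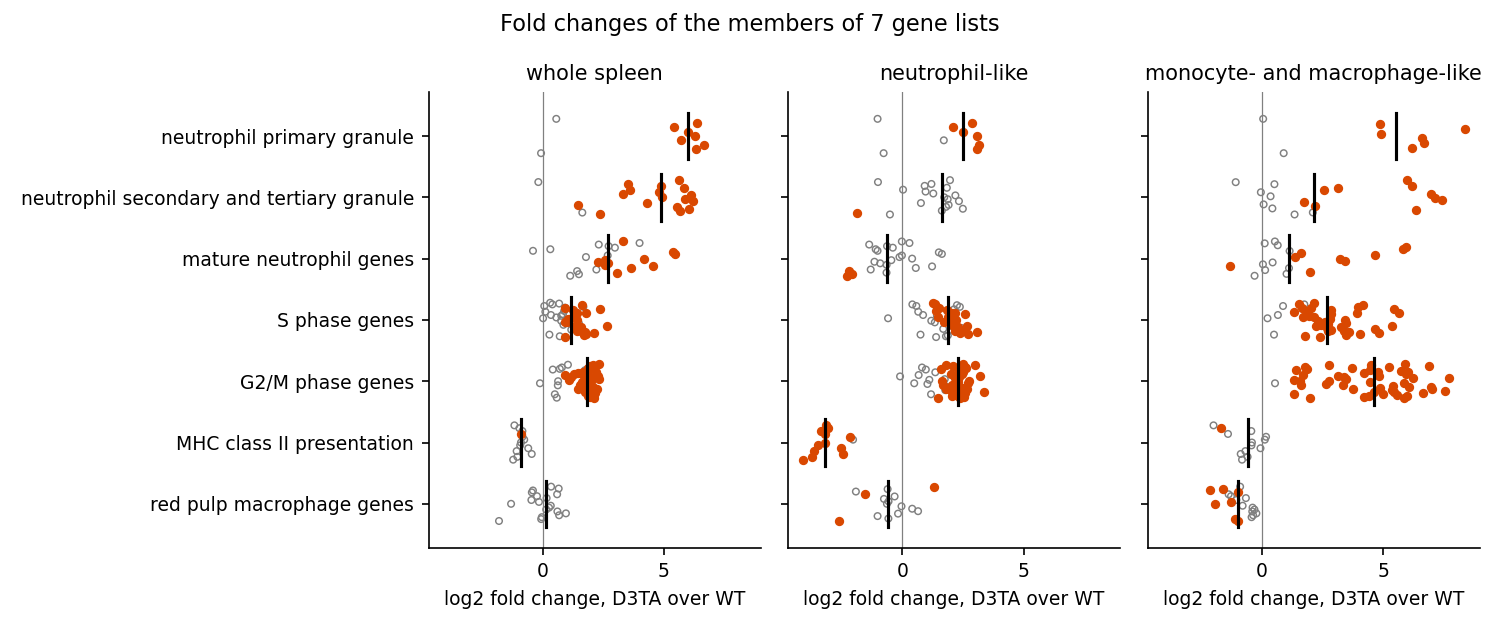
Log2 fold change, D3TA over WT (horizontal axis), of the members of 7 gene lists (vertical axis) in the whole spleen, neutrophil-like cells and monocyte- and macrophage-like cells; filled points passed edgeR's adjusted p of 0.05, open points did not, and black lines mark list medians. Ms4a3 and Itgb2l had 0 WT UMIs in the monocyte- and macrophage-like cells and are drawn at their fitted values, which depend on the prior count. The G2/M medians were 1.84, 2.30 and 4.62 in the 3 panels.

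Further lists of the whole spleen describe inflammation, stress and metabolism. Of 29 AP-1 and heat shock stress genes, 11 rose, such as Fos (2.66 ± 0.19) and Hspa1a (3.10 ± 0.24), 18 passed within the list and the list passed (camera adjusted p = 6.84e-07, against 0.408 with an estimated correlation). These respond to tissue handling as well as to stimuli. Of 22 progenitor genes, 5 rose, such as the transcription factor genes Erg (5.04 ± 0.22) and Hlf (3.42 ± 0.31), 8 passed within the list and the list passed (camera adjusted p = 2.75e-04, against 0.408 with an estimated correlation). Of 18 suppressive myeloid cell genes, 5 rose, such as Chil3 (5.52 ± 0.43) and Trem1 (3.31 ± 0.39), 13 passed within the list and the list passed (camera adjusted p = 1.38e-04, against 0.408 with an estimated correlation). This list shares members with the neutrophil lists. Of 20 glycolysis genes, 7 rose, such as the hexokinase genes Hk3 (3.76 ± 0.24) and Hk2 (1.88 ± 0.22), 16 passed within the list and the list passed (camera adjusted p = 2.79e-06, against 0.408 with an estimated correlation). Of 19 JAK-STAT targets, 2 rose, such as Cebpd (3.68 ± 0.41) and Osm (2.41 ± 0.27), 5 passed within the list and the list passed (camera adjusted p = 0.00656, against 0.53 with an estimated correlation). Of 7 NADPH oxidase genes, 2 rose, such as Ncf1 (1.59 ± 0.18) and Cybb (1.46 ± 0.24), 3 passed within the list and the list passed (camera adjusted p = 0.00178, against 0.461 with an estimated correlation). Of 28 NF-kB and inflammatory cytokine genes, 4 rose and 1 fell, such as Clec4e (3.05 ± 0.40) and Nfkbiz (1.01 ± 0.17), 5 passed within the list and the list passed (camera adjusted p = 0.0443, against 0.554 with an estimated correlation). The fall was that of Relb (-0.82 ± 0.14, edgeR adjusted p = 0.041), a gene chosen after its values were seen. Relb, Hk2, Nfkbiz, Ncf1 and Cybb missed the threshold without WT replicate 1 (edgeR adjusted p = 0.445, 0.0657, 0.487, 0.196 and 0.453). Relb, Hk2, Osm, Clec4e, Nfkbiz, Ncf1 and Cybb missed the threshold without WT replicate 2 (edgeR adjusted p = 0.387, 0.0941, 0.0691, 0.0647, 0.299, 0.20 and 0.263). For the JAK-STAT and the NF-kB lists, camera's adjusted p was 0.0681 and 0.519 without D3TA replicate 1.

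Lists of lymphoid, erythroid and housekeeping genes completed the whole-spleen comparison. Of 13 MHC class II presentation genes, 1 fell, namely H2-DMb2 (-0.92 ± 0.17), and 13 passed within the list (median log2 fold change -0.92, camera adjusted p = 5.55e-07, against 0.408 with an estimated correlation). Of 12 germinal center B cell genes, 3 fell, among them Rgs13 (-2.92 ± 0.42) and the BAFF receptor gene Tnfrsf13c (-0.80 ± 0.15), and 7 passed within the list (median log2 fold change -0.79, camera adjusted p = 5.04e-05, against 0.408 with an estimated correlation). Of 82 ribosomal protein genes, edgeR called 0, and 0 passed within the list (median log2 fold change -0.32, camera adjusted p = 1.48e-06, against 0.53 with an estimated correlation). Of 26 heme and erythroid genes, edgeR called 0, and 0 passed within the list (median log2 fold change 0.55, camera adjusted p = 4.86e-04, against 0.554 with an estimated correlation). Of 16 platelet and megakaryocyte genes, 1 rose, namely Pf4 (2.28 ± 0.38), and 1 passed within the list (median log2 fold change 0.61, camera adjusted p = 0.00763, against 0.408 with an estimated correlation). Of 23 T cell activation and exhaustion genes, edgeR called 0, and 2 passed within the list (median log2 fold change 0.85, camera adjusted p = 0.00645, against 0.554 with an estimated correlation). Of 77 oxidative phosphorylation genes, 1 rose, namely Cox6b2 (1.42 ± 0.24), and 0 passed within the list (median log2 fold change 0.37, camera adjusted p = 3.59e-05, against 0.585 with an estimated correlation). Camera did not separate from other genes the p53 targets (0 of 19 called by edgeR, and 2 within the list, adjusted p = 0.0797) or the mitochondrially encoded genes (0 of 13 called by edgeR, and 0 within the list, adjusted p = 0.0777). The same held for the age-associated B cell genes (1 of 15 called by edgeR, and 1 within the list, adjusted p = 0.479) and the red pulp macrophage genes (0 of 19 called by edgeR, and 0 within the list, adjusted p = 0.698). The red pulp list had a median of 0.14 but a mean of -0.01, and its test pointed down. Itgam, a myeloid integrin gene of the age-associated list chosen after its values were seen, rose (2.90 ± 0.37, edgeR adjusted p = 0.0188). It also held for the interferon response genes (0 of 33 called by edgeR, and 0 within the list, adjusted p = 0.479), whose test pointed down although their median was 0.14. Their camera adjusted p was 3.78e-06 and lower without D3TA replicate 1, and 0.00477 and higher without D3TA replicate 2. For the heme and the T cell activation lists, camera's adjusted p was 0.141 and 0.11 without WT replicate 1. For the platelet and the T cell activation lists, camera's adjusted p was 0.172 and 0.414 without D3TA replicate 1. Without WT replicate 2, the age-associated list was higher (camera adjusted p = 0.00761). Without D3TA replicate 1, the red pulp list was lower (camera adjusted p = 0.0296). Without D3TA replicate 2, the mitochondrial list was lower (camera adjusted p = 0.0284). H2-DMb2, Tnfrsf13c, Pf4, Cox6b2 and Itgam missed the threshold without WT replicate 1 (edgeR adjusted p = 0.401, 0.551, 0.153, 0.262 and 0.0513). H2-DMb2, Rgs13, Tnfrsf13c, Pf4 and Cox6b2 missed the threshold without WT replicate 2 (edgeR adjusted p = 0.462, 0.0677, 0.373, 0.0741 and 0.103). Pf4 and Cox6b2 missed the threshold without D3TA replicate 1 (edgeR adjusted p = 0.0727 and 0.0646).

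Among neutrophil-like cells alone, all stages together, the question was which genes differed between D3TA and WT cells of the lineage. Genes of mitosis rose in the D3TA cells, cyclin B1, Ccnb1, from 7.21 ± 2.04 to 66.3 ± 9.91 CPM (SD, n = 2, log2 fold change 3.28 ± 0.38, edgeR adjusted p = 0.016). The microtubule regulator Gas2l3 (3.46 ± 0.42, adjusted p = 0.016), the kinesin Kif2c (3.21 ± 0.71, adjusted p = 0.0297) and the condensin subunit Ncaph (3.15 ± 0.59, adjusted p = 0.0204) rose with it. So did the abscission gene Cep55 (3.03 ± 0.44, adjusted p = 0.016) and the kinase genes Pbk (3.07 ± 0.56, adjusted p = 0.0194) and Ttk (2.98 ± 0.60, adjusted p = 0.024). The primary granule genes Elane (3.16 ± 0.50, adjusted p = 0.0164), Mpo (3.08 ± 0.57, adjusted p = 0.0194) and Ctsg (3.07 ± 0.46, adjusted p = 0.0162) rose in the same fit. Prr11 (3.17 ± 0.67, adjusted p = 0.0261) and Astn2 (4.75 ± 0.97, adjusted p = 0.0245) completed the 12 largest rises. The chemokine gene Cxcl2 fell from 106 ± 46.9 to 11.7 ± 3.98 CPM (-3.17 ± 0.43, edgeR adjusted p = 0.016), and so did the interferon-induced genes Ifit3 (-3.39 ± 0.90, adjusted p = 0.0478) and Ifi209 (-3.23 ± 0.57, adjusted p = 0.019). Sirpb1c (-3.05 ± 0.34, adjusted p = 0.016), Vnn3 (-3.33 ± 0.46, adjusted p = 0.016) and Chrm3 (-3.10 ± 0.42, adjusted p = 0.016) fell too. Sh3pxd2a (-4.16 ± 0.62, adjusted p = 0.0162) and Pgap1 (-4.01 ± 0.93, adjusted p = 0.0333) were also among the 12 largest falls. These falls also held genes of B cells, Fcer2a, which encodes CD23 (-4.53 ± 1.01), Vpreb3 (-4.20 ± 0.67), Zfp318 (-3.69 ± 0.61) and the follicular chemokine receptor Cxcr5 (-2.91 ± 0.49). The B cell marker Cd79a stood at 521 and 124 CPM in the neutrophil-like cells of WT replicates 1 and 2 and at 16.9 and 24.3 CPM in those of D3TA replicates 1 and 2. Ccnd2 had a log2 fold change of -2.13 ± 0.35 (edgeR adjusted p = 0.0171) and was among the genes for which free RNA was held possible. Astn2, Kif2c, Prr11 and Ccnd2 missed the threshold without D3TA replicate 2 (edgeR adjusted p = 0.0813, 0.0613, 0.0591 and 0.0629). Kif2c, Ttk, Pgap1 and Ccnd2 missed the threshold without D3TA replicate 1 (edgeR adjusted p = 0.0568, 0.0511, 0.0615 and 0.055).

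In these neutrophil-like cells, edgeR called 1628 of 12896 genes, 616 higher and 1012 lower, and DESeq2 called 2033 (828 higher, 1205 lower). Of the genes called by edgeR, 1001 (526 higher, 475 lower) were expressed at 1 part in 5 or more of their level in the class where they were highest. Under that limit, free RNA from other cells was held possible. The libraries of the groups did not overlap in 62.5% of all tested genes (33.3% by chance). The fit compares lineages of different stage mix, since immature cells made up most of the D3TA and few of the WT cells. The count was 4849 (2603 higher, 2246 lower) without WT replicate 2, 248 (61 higher, 187 lower) without D3TA replicate 1 and 406 (106 higher, 300 lower) without D3TA replicate 2, and WT replicate 2 held 158 of the cells.

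By list, the neutrophil-like cells of D3TA spleens, of another stage mix than the WT cells, carried more transcripts of the cell cycle and of primary granules and fewer of inflammation by camera, but not with an estimated correlation (adjusted p = 0.651). In mature cells alone, the lists of G2/M phase and primary granule genes passed (camera adjusted p = 0.00281 and 7.92e-07), and those of S phase, NF-kB and interferon response genes did not (median log2 fold changes 0.05, -0.11 and 0.29, camera adjusted p = 0.193, 0.692 and 0.787). Of 51 G2/M phase genes, 38 rose, such as the mitotic phosphatase gene Cdc25c (3.37 ± 0.51) and Cdc20 (2.57 ± 0.35), and 47 passed within the list (median log2 fold change 2.30, camera adjusted p = 2.52e-15, against 0.651 with an estimated correlation). Of 43 S phase genes, 23 rose, such as Ccne2 (2.72 ± 0.50) and E2f8 (2.65 ± 0.50), and 35 passed within the list (median log2 fold change 1.89, camera adjusted p = 1.86e-10, against 0.651 with an estimated correlation). Of 9 primary granule genes, 6 rose, among them Ms4a3 (2.51 ± 0.41), and 7 passed within the list (median log2 fold change 2.51, camera adjusted p = 0.00252, against 0.651 with an estimated correlation). Of 19 secondary and tertiary granule genes, 1 fell, namely the arginase gene Arg2 (-1.86 ± 0.34), and 1 passed within the list (median log2 fold change 1.63, camera adjusted p = 0.0184, against 0.651 with an estimated correlation). Of 24 NF-kB and inflammatory cytokine genes, 10 fell, such as the cyclooxygenase gene Ptgs2 (-2.57 ± 0.36) and the inflammasome gene Nlrp3 (-2.17 ± 0.36), and 15 passed within the list (median log2 fold change -1.47, camera adjusted p = 1.28e-05, against 0.651 with an estimated correlation). Of 32 interferon response genes, 8 fell, such as Rsad2 (-2.59 ± 0.57), and 8 passed within the list (median log2 fold change -0.71, camera adjusted p = 2.79e-04, against 0.651 with an estimated correlation). Of 76 oxidative phosphorylation genes, 6 rose, such as the complex I genes Ndufv3 (1.52 ± 0.31) and Ndufb2 (1.40 ± 0.30), and 25 passed within the list (median log2 fold change 0.87, camera adjusted p = 5.95e-11, against 0.651 with an estimated correlation). For the secondary and tertiary granule list, camera's adjusted p was 0.30 without WT replicate 1. For the interferon list, camera's adjusted p was 0.106 without D3TA replicate 2. Cdc25c, Ccne2, Arg2, Ndufv3 and Ndufb2 missed the threshold without D3TA replicate 1 (edgeR adjusted p = 0.0564, 0.0556, 0.0735, 0.147 and 0.244). The same genes also missed it without D3TA replicate 2 (edgeR adjusted p = 0.089, 0.0591, 0.104, 0.089 and 0.115).

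Lists of antigen-presenting and B cells were lower in the neutrophil-like cells of D3TA spleens by camera, but not with an estimated correlation (adjusted p = 0.651 for each). Of 13 MHC class II genes, 12 fell, such as Ciita (-3.62 ± 0.59) and Cd40 (-4.09 ± 0.70). Within the list, 13 passed (median log2 fold change -3.19, camera adjusted p = 9.11e-07). Of 15 age-associated B cell genes, 1 rose and 7 fell, with falls in Itgax (-2.99 ± 0.36) and Cd80 (-2.38 ± 0.31). Within the list, 12 passed (median log2 fold change -2.0, camera adjusted p = 0.00748). Of 11 germinal center B cell genes, 4 fell, among them the BAFF receptor gene Tnfrsf13c (-3.71 ± 0.58). Within the list, 8 passed (median log2 fold change -1.61, camera adjusted p = 0.00157). Cluster 13, next closest to B cells, gave 994 of 1187 and 20 of 158 neutrophil-like cells of WT replicates 1 and 2. Cd79a, a B cell gene chosen after its values were seen, fell too (-3.98 ± 0.66, edgeR adjusted p = 0.0172), and free RNA was held possible for it. RNA of B cells was not separated from these falls in neutrophil-like cells. The other 15 lists did not pass camera in these cells with all 4 libraries. Without WT replicate 1, the heme list was higher (camera adjusted p = 0.00707) and the mature neutrophil, JAK-STAT, stress and suppressive lists were lower (camera adjusted p = 0.00375, 0.0184, 0.0439 and 0.0198). Without WT replicate 2, the cyclin D, NADPH oxidase, progenitor and glycolysis lists were higher (camera adjusted p = 0.00924, 0.0271, 0.0122 and 0.0106) and the ribosomal list was lower (camera adjusted p = 0.0121). Without D3TA replicate 1, the glycolysis list was higher (camera adjusted p = 0.0233) and the mature neutrophil, JAK-STAT, suppressive and T cell activation lists were lower (camera adjusted p = 0.00389, 0.0036, 0.00717 and 0.00389). Without D3TA replicate 2, the glycolysis list was higher (camera adjusted p = 0.00617). For the germinal center list, camera's adjusted p was 0.0501 without WT replicate 1 and 0.0857 without D3TA replicate 2.

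Mature neutrophil-like cells were also compared alone, a fit added after the data were seen because the stage mix differed. The mix still differed, since cluster 17, with the granule genes Mmp8, Lcn2 and Ngp among its leading genes, gave 1.53% and 9.19% of the UMIs of WT and 59.2% and 61.6% of those of D3TA replicates 1 and 2. In the mature cells of D3TA spleens the formyl peptide receptor genes Fpr1 (2.33 ± 0.42, adjusted p = 0.0315) and Fpr2 (2.40 ± 0.44, adjusted p = 0.0315) rose. Cybb, the catalytic subunit of the phagocyte NADPH oxidase, rose from 183 ± 45.4 to 1044 ± 234 CPM (SD, n = 2, 2.52 ± 0.46, edgeR adjusted p = 0.0315). The granule and surface genes Itgb2l (4.86 ± 0.71, adjusted p = 0.0297), Elane (4.53 ± 0.62, adjusted p = 0.0297), Cd177 (3.77 ± 0.82, adjusted p = 0.0379) and Chil3 (3.67 ± 0.81, adjusted p = 0.0385) rose as well. They rose together with Acvrl1 (4.73 ± 0.63, adjusted p = 0.0297), a receptor of the TGF-beta family, and Pabpc1l (4.02 ± 0.49, adjusted p = 0.0289). Gpr27 and Inhba had 1 UMI each over the WT cells, and their UMI rates were 139.8 times (24.997 to 5533) and 79.4 times (14.2 to 3148) as high in the D3TA cells (counting intervals). Mpo, with 0 WT UMIs, was at least 41.9-fold higher, against a floor of 3 UMIs over the group. Background RNA of precursors is not separated from these primary granule values, since Mpo stood at 54.9 and 69.9 and Elane at 51.7 and 45.4 CPM in mature cells of D3TA replicates 1 and 2, against 18.04 and 31.4 and 16.4 and 17.6 CPM in their B-cell-like cells. Precursor-like cells held Mpo at 5331 and 7744 CPM in these libraries, and the free RNA limit, which sets no neutrophil stage against another, does not cover this source. Fcer2a (-4.26 ± 0.90), the sialyltransferase gene St6gal1 (-3.51 ± 0.76) and Ifi209 (-3.26 ± 0.63) were among the largest falls. BE692007, Rapgef4, Sh3pxd2a, the sulfotransferase gene Chst3 and Zfp318 also fell. edgeR called 715 of 9151 genes, 275 higher and 440 lower, of which 351 (237 higher, 114 lower) were above the free RNA limit. With doublets kept it called 829 (497 higher, 332 lower). DESeq2 called 773 (333 higher, 440 lower), and the count by edgeR was 153 (103 higher, 50 lower) without WT replicate 1, 2974 (1417 higher, 1557 lower) without WT replicate 2, 205 (95 higher, 110 lower) without D3TA replicate 1 and 375 (124 higher, 251 lower) without D3TA replicate 2. Fpr1, Fpr2 and Cybb missed the threshold without D3TA replicate 1 (edgeR adjusted p = 0.0796, 0.0642 and 0.151). Fpr2 and Cybb missed the threshold without D3TA replicate 2 (edgeR adjusted p = 0.103 and 0.194). Fcer2a, St6gal1, Ifi209, Rapgef4, Sh3pxd2a and Zfp318 missed the threshold without WT replicate 1 (edgeR adjusted p = 0.177, 0.132, 0.112, 0.109, 0.0725 and 0.0704). Most WT cells of this stage came from cluster 13 of WT replicate 1, with a median of 950 UMIs per cell and B cell as its next closest class.

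Gene lists of granules, glycolysis and antigen presentation differed in mature neutrophil-like cells by camera, but not with an estimated correlation (adjusted p = 0.727 for each). Of 9 primary granule genes in mature cells, 6 rose, 6 passed within the list and the list passed (camera adjusted p = 7.92e-07). Of 19 secondary and tertiary granule genes, 8 rose, and 14 passed within the list (median log2 fold change 2.86, camera adjusted p = 5.78e-11). Free RNA was held possible for 6 of the 9 primary granule genes, and granule lists were higher in B-, T- and erythroid-like cells of the D3TA libraries too. Summed over the 19 secondary and tertiary granule genes, CPM was 5504 and 14839.7 in WT and 38287 and 42340.4 in D3TA libraries. Over the 9 primary genes the sums overlapped, at 2807 and 4728 against 3979 and 4435. Within cluster 10 alone, looked at after the data were seen and with no test, the former was 10872 and 10093 against 14291 and 12000.4. Much of its difference thus goes with the mix of clusters. The latter was 5265 and 5463 against 6733 and 8518 there. Of 23 mature neutrophil genes, 4 rose, and 6 passed within the list (median log2 fold change 1.12, camera adjusted p = 2.99e-07, against 0.727 with an estimated correlation). Of 18 glycolysis genes, 4 rose, such as Pgk1 (1.71 ± 0.33) and Ldha (1.34 ± 0.31). Within the list, 14 passed (median log2 fold change 1.19, camera adjusted p = 5.05e-07). Of 13 MHC class II genes, 10 fell, among them H2-Aa (-2.95 ± 0.60). Within the list, 11 passed (median log2 fold change -2.80, camera adjusted p = 5.05e-07). RNA of B cells moved the same way, with Cd79a, chosen after its values were seen, at 536 and 162 CPM in mature cells of WT replicates 1 and 2 and at 36.6 and 41.4 CPM in those of D3TA replicates 1 and 2, and free RNA was held possible for 13 of the 13 MHC class II genes. Of 81 ribosomal protein genes, edgeR called 0, and 0 passed within the list (median log2 fold change -1.26, camera adjusted p = 1.41e-08, against 0.822 with an estimated correlation). The G2/M, NADPH oxidase, JAK-STAT, platelet and suppressive lists also passed camera (adjusted p = 0.00281, 0.00208, 0.0163, 0.0234 and 6.51e-04, against 0.727 to 0.81 with an estimated correlation). The other 14 lists did not pass with all 4 libraries. For the G2/M, the JAK-STAT and the platelet lists, camera's adjusted p was 0.265, 0.328 and 0.101 in mature cells without WT replicate 1. For the JAK-STAT and the platelet lists, camera's adjusted p was 0.0698 and 0.0813 in mature cells without D3TA replicate 1. Without WT replicate 1, the S phase, heme, mitochondrial and oxidative phosphorylation lists were higher (camera adjusted p = 0.00118, 0.0184, 0.0206 and 0.00161). Without WT replicate 2, the stress list was higher (camera adjusted p = 0.0133) and the mitochondrial list was lower (camera adjusted p = 0.0235). Without D3TA replicate 1, the stress list was higher (camera adjusted p = 0.042) and the interferon and T cell activation lists were lower (camera adjusted p = 3.60e-04 and 0.042). Without D3TA replicate 2, the interferon, heme and oxidative phosphorylation lists were higher (camera adjusted p = 1.38e-04, 0.0347 and 0.0055). Pgk1, Ldha and H2-Aa missed the threshold without D3TA replicate 1 (edgeR adjusted p = 0.253, 0.483 and 0.253). Pgk1, Ldha and H2-Aa missed the threshold without D3TA replicate 2 (edgeR adjusted p = 0.176, 0.386 and 0.157). Ldha missed the threshold without WT replicate 1 (edgeR adjusted p = 0.0513).

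Monocyte- and macrophage-like cells of D3TA spleens had higher levels of many cell-cycle genes than those of WT spleens. Cdk1, the kinase that drives entry into mitosis, had 3 UMIs over the WT and 1042 over the D3TA cells, a UMI rate 132 times (45.1 to 642) as high (exact counting interval, edgeR adjusted p = 1.58e-04). The histone gene Hist1h1a, Shcbp1 and the repressor gene E2f7 had 0 UMIs over the WT cells. They were at least 60.4-fold, 50.5-fold and 38.8-fold higher in D3TA cells, against a floor of 3 UMIs over the group (edgeR adjusted p = 0.00157, 2.69e-04 and 3.57e-04). The UMI rate of the motility receptor gene Hmmr was 236 times (42.3 to 9352) as high, that of Cdca3 203 times (55.98 to 1676) and that of the histone gene Hist1h3c 148 times (40.9 to 1225). The chemokine gene Ccl8 (chromosome 11, 82115185 to 82116799) was 391 times (108 to 3234) as high. Timd4, a receptor for apoptotic cells on resident macrophages (chromosome 11, 46810800 to 46844332), fell from 55.8 ± 8.16 to 11.7 ± 11.2 CPM (SD, n = 2, -2.14 ± 0.54, edgeR adjusted p = 0.0425). The lysozyme gene Lyz1 (-4.71 ± 0.73, adjusted p = 0.00474), the interferon-induced gene Ifi213 (-3.16 ± 0.58, adjusted p = 0.0104) and Gpm6b (-2.29 ± 0.39, adjusted p = 0.00728) fell with it. Lymphotoxin beta, Ltb (-2.12 ± 0.44, adjusted p = 0.0191), and the peptide transporter Slc15a2 (-2.08 ± 0.45, adjusted p = 0.0244) fell as well. The histone demethylase Kdm5b (-2.05 ± 0.40, adjusted p = 0.0141) and the sialyltransferase St8sia6 (-2.04 ± 0.29, adjusted p = 0.00309) completed the 8 largest falls. Of the cyclin D and CDK genes, Ccnd1 (-1.55 ± 0.38, adjusted p = 0.0395) fell and Cdk4 (1.32 ± 0.31, adjusted p = 0.0325) rose, while Ccnd2 (-0.78 ± 0.47, 0.338) and Cdk6 (-0.23 ± 0.28, 0.662) did not pass. Ccnd2 passed without D3TA replicate 1 (edgeR adjusted p = 0.015). Lyz1, the histone genes and the Ifi genes have near-identical relatives, between which counting can divide reads. Ccl8, Timd4, Ltb, Slc15a2, Kdm5b, Ccnd1 and Cdk4 missed the threshold without WT replicate 1 (edgeR adjusted p = 0.0994, 0.12, 0.127, 0.173, 0.0505, 0.385 and 0.201). Ccl8, Slc15a2 and Cdk4 missed the threshold without D3TA replicate 1 (edgeR adjusted p = 0.187, 0.0542 and 0.0947). Cdk4 missed the threshold without WT replicate 2 (edgeR adjusted p = 0.119).

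In this class edgeR called 969 of 10644 genes, 682 higher and 287 lower, and DESeq2 called 895 (624 higher, 271 lower). Of the genes called by edgeR, 793 (591 higher, 202 lower) were above the free RNA limit. The libraries of the groups did not overlap in 55.8% of tested genes (33.3% by chance). Monocyte-like cells of WT replicate 1 lay mostly in cluster 35 and those of the other libraries in cluster 25. Within cluster 25 alone, G2/M phase genes took 1217 and 1439 CPM in WT and 12281 and 11039.5 in D3TA replicates 1 and 2. The count was 395 (344 higher, 51 lower) without WT replicate 1 and 2239 (1441 higher, 798 lower) without D3TA replicate 2.

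**Figure D4:**
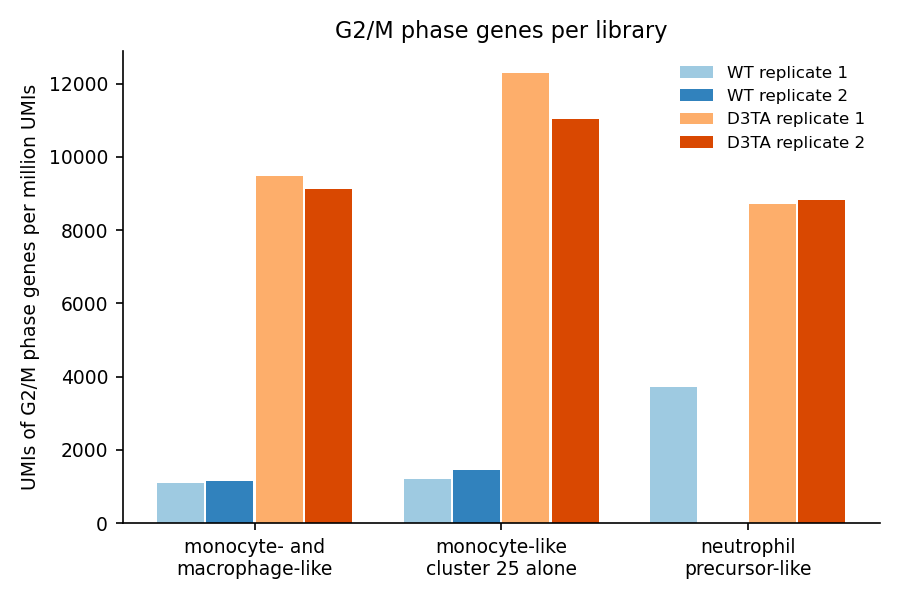
CPM of 51 G2/M phase genes together (vertical axis) in each library for monocyte- and macrophage-like cells, for monocyte-like cluster 25 alone and for neutrophil precursor-like cells; WT replicate 2 has no precursor bar because it held 1 such cell. In the monocyte- and macrophage-like cells the bars stood at 1100.5 and 1150.1 in WT and at 9466 and 9111 in D3TA libraries.

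By list, cell-cycle genes were higher and red pulp macrophage genes lower in monocyte- and macrophage-like cells by camera, but not with an estimated correlation (adjusted p = 0.23 to 0.315). Of 51 G2/M phase genes, 50 rose, such as the topoisomerase gene Top2a (5.25 ± 0.33) and Mki67 (5.94 ± 0.37), and 50 passed within the list (median log2 fold change 4.62, camera adjusted p = 4.75e-47, against 0.23 with an estimated correlation). Of 43 S phase genes, 38 rose, such as the replicative helicase gene Mcm5 (3.44 ± 0.29) and E2f8 (5.37 ± 0.39), and 41 passed within the list (median log2 fold change 2.67, camera adjusted p = 2.24e-30, against 0.23 with an estimated correlation). Of 24 cyclin D, CDK and RB pathway genes, 9 rose and 1 fell, with rises in the CDK inhibitor genes Cdkn2c (3.42 ± 0.35) and Cdkn1a (2.78 ± 0.40), and 11 passed within the list (median log2 fold change 0.26, camera adjusted p = 0.0163, against 0.338 with an estimated correlation). Of 19 red pulp macrophage genes, 7 fell, such as Hpgd (-1.93 ± 0.32), Treml4 (-1.62 ± 0.27), the integrin gene Itgad (-1.25 ± 0.28) and the receptor kinase gene Axl (-1.10 ± 0.26), and 12 passed within the list (median log2 fold change -1.0, camera adjusted p = 9.58e-07, against 0.315 with an estimated correlation). Macrophage-like cells gave 57.1% and 49.5% of the UMIs of this joint class in WT replicates 1 and 2 and 24.9% and 21.9% in D3TA replicates 1 and 2. Within macrophage-like cells alone, looked at after the data were seen and with no test, the 19 genes had a median log2 ratio of mean CPM of 0.16, and the 7 that fell in the joint class one of -0.22. Of these 7, 2, Timd4 and Treml4, were lower in both D3TA than in both WT libraries (16.7% by chance). Of 8 primary granule genes, 6 rose, 7 passed within the list and the list passed (camera adjusted p = 1.16e-07, against 0.315 with an estimated correlation). Their median log2 fold change was 4.89 with Ms4a3, at 0 WT UMIs, set to its bound, against 5.55 as fitted. Of 18 secondary and tertiary granule genes, 10 rose, such as Ngp (6.18 ± 0.40), and 12 passed within the list (median log2 fold change 2.14, camera adjusted p = 1.82e-08, against 0.23 with an estimated correlation). Of 19 mature neutrophil genes, 8 rose and 1 fell, with a rise in S100a8 (5.80 ± 0.78), and 11 passed within the list (median log2 fold change 1.12, camera adjusted p = 4.29e-05, against 0.338 with an estimated correlation). Without the genes of possible free RNA, camera's adjusted p was 0.199 for the secondary and tertiary granule, 0.515 for the mature neutrophil, 0.0579 for the cyclin D and 1.11e-51 for the G2/M list. Of 28 AP-1 and heat shock stress genes, 8 rose, such as Fosb (3.45 ± 0.44) and Jun (2.22 ± 0.33), and 16 passed within the list (median log2 fold change 0.67, camera adjusted p = 1.59e-04, against 0.338 with an estimated correlation). Itgad, Axl and Jun missed the threshold without WT replicate 1 (edgeR adjusted p = 0.318, 0.33 and 0.057). Itgad and Axl missed the threshold without WT replicate 2 (edgeR adjusted p = 0.0818 and 0.148) and without D3TA replicate 1 (0.0542 and 0.068).

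Other lists passed camera in monocyte- and macrophage-like cells with few called members. Of 16 suppressive myeloid cell genes, 5 rose, such as the chitinase-like gene Chil3 (2.18 ± 0.40), and 7 passed within the list (median log2 fold change 0.54, camera adjusted p = 0.00817, against 0.567 with an estimated correlation). Of 75 oxidative phosphorylation genes, 8 rose, such as Cox6a1 (1.15 ± 0.26), and 32 passed within the list (median log2 fold change 0.74, camera adjusted p = 1.59e-11, against 0.567 with an estimated correlation). Of 18 glycolysis genes, 4 rose, such as Tpi1 (1.40 ± 0.31), and 5 passed within the list (median log2 fold change 0.65, camera adjusted p = 0.00817, against 0.567 with an estimated correlation). Of 33 interferon response genes, 4 fell, such as Slfn5 (-1.17 ± 0.25) and Ifit3 (-1.85 ± 0.40), and 6 passed within the list (median log2 fold change -0.24, camera adjusted p = 0.00366, against 0.593 with an estimated correlation). Of 13 MHC class II presentation genes, 1 fell, namely H2-Oa (-1.68 ± 0.44), and 5 passed within the list (median log2 fold change -0.59, camera adjusted p = 0.00614, against 0.567 with an estimated correlation). Of 6 platelet and megakaryocyte genes, 2 fell, namely Vwf (-2.29 ± 0.50) and Pdgfb (-1.45 ± 0.38), and 3 passed within the list (median log2 fold change -0.92, camera adjusted p = 0.0224, against 0.567 with an estimated correlation). The other 11 lists did not pass camera here with all 4 libraries. Without D3TA replicate 1, the ribosomal list was lower (camera adjusted p = 6.88e-04). Without D3TA replicate 2, the NADPH oxidase, JAK-STAT and ribosomal lists were higher (camera adjusted p = 0.0317, 0.0161 and 0.0161) and the progenitor list was lower (camera adjusted p = 0.0317). For the glycolysis list, camera's adjusted p was 0.0633 without WT replicate 1. For the interferon and the platelet lists, camera's adjusted p was 0.0617 and 0.447 without WT replicate 2. For the suppressive list, camera's adjusted p was 0.117 without D3TA replicate 1. For the interferon, the MHC class II and the platelet lists, camera's adjusted p was 0.956, 0.339 and 0.327 without D3TA replicate 2. Slfn5, Cox6a1, Tpi1, Chil3, Vwf and H2-Oa missed the threshold without WT replicate 1 (edgeR adjusted p = 0.177, 0.309, 0.275, 0.145, 0.125 and 0.378). Slfn5, Ifit3, Cox6a1, Tpi1, Vwf and Pdgfb missed the threshold without WT replicate 2 (edgeR adjusted p = 0.145, 0.0699, 0.196, 0.068, 0.126 and 0.312). Vwf, Pdgfb and H2-Oa missed the threshold without D3TA replicate 1 (edgeR adjusted p = 0.0651, 0.105 and 0.125). Vwf missed the threshold without D3TA replicate 2 (edgeR adjusted p = 0.0537).

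In B-cell-like, T-cell-like and erythroid-like cells of D3TA spleens, secondary and tertiary granule genes, which these cells are not known to make, were higher as a list by camera (adjusted p = 1.40e-20, 1.79e-16 and 8.95e-19) but not with an estimated correlation (adjusted p = 0.559, 0.523 and 0.77). For this list edgeR called 0 of 19, 18 and 16 members, 13, 10 and 13 passed within the list, and the median log2 fold changes were 3.48, 3.83 and 5.26. G2/M phase genes in B-cell-like and in T-cell-like cells and T cell activation genes in T-cell-like cells were higher by camera (adjusted p = 1.01e-14, 6.34e-17 and 4.08e-07) but not with an estimated correlation (adjusted p = 0.559, 0.575 and 0.575). In the same order, edgeR called 0 of 51, 51 and 23 members, 0, 0 and 3 passed within the list, and the median log2 fold changes were 3.04, 1.64 and 1.24. Over 25 lists, camera called 14, 16 and 11 in B-cell-like, T-cell-like and erythroid-like cells, and 0 in each with an estimated correlation. In WT replicate 1, cluster 1, of low UMI counts, held 56.3% of B-cell-like and cluster 2 77.8% of T-cell-like cells. In D3TA replicate 1, cluster 39, with the proliferation gene Pclaf and S phase histone genes among its leading genes, gave 32.1% of the UMIs of B-cell-like cells. edgeR called 0 of 15117 genes in B-cell-like cells, with 832 at an unadjusted p under 0.05 and 228 (220 higher, 8 lower) called by DESeq2. It called 0 of 13794 genes in T-cell-like cells, with 839 at an unadjusted p under 0.05 and 149 (115 higher, 34 lower) called by DESeq2. It called 0 of 11416 genes in erythroid-like cells, with 606 at an unadjusted p under 0.05 and 90 (22 higher, 68 lower) called by DESeq2. The libraries of the groups did not overlap in 34.6%, 31.9% and 31.02% of the genes of these classes, against 33.3% by chance. In erythroid-like cells the heme and erythroid list did not pass (0 of 26 called, and 0 within the list, camera adjusted p = 0.157). On simulated data, without effects of a single mouse, edgeR recovered 51% of 4-fold and 6% of 2-fold changes among 15117 genes of B-cell-like cells. It recovered 66% and 15% in T-cell-like and 78% and 19% in erythroid-like cells. The count for B-cell-like cells was 3 (3 higher, 0 lower) without WT replicate 1 and 3012 (1800 higher, 1212 lower) without D3TA replicate 2, that for T-cell-like cells 95 (89 higher, 6 lower) without WT replicate 1 and 416 (230 higher, 186 lower) without WT replicate 2 and that for erythroid-like cells 2 (2 higher, 0 lower) without D3TA replicate 2. For the T cell activation list, camera's adjusted p was 0.117 in T-cell-like cells without D3TA replicate 1. The heme list was lower without WT replicate 1 and without D3TA replicate 1 (camera adjusted p = 2.26e-07 and 3.95e-04).

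Whether the genotype effect differed between neutrophil-like and B-cell-like cells was tested directly, as a class-by-genotype interaction with the mouse as a term. Of the cyclin D and CDK genes, Ccnd3 had a difference of -0.53 ± 0.46 (adjusted p = 0.60) on the log2 scale, neutrophil-like minus B-cell-like, and Ccnd2 -3.08 ± 0.54 (adjusted p = 0.105), both by edgeR. Cdk4 had 0.73 ± 0.42 (adjusted p = 0.422) and Cdk6 1.70 ± 0.46 (adjusted p = 0.166). edgeR called 0 of 15964 genes, with 2589 at an unadjusted p under 0.05, and DESeq2 was not run on this term. The count was 479 without WT replicate 2, 619 without D3TA replicate 1 and 662 without D3TA replicate 2, each with a single mouse in 1 group that is assumed to vary like the others.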

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

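Tests with unnamed clusters counted by closest class, crossed pairing or mature neutrophil-like cells alone were chosen after the data were seen. Called genes in the whole spleen numbered 1108, and 2439 by DESeq2. In neutrophil-like cells they numbered 1628, and 2487 with doublets kept, 820 with unnamed clusters counted with their closest class and 3062 with no filter on low counts. In monocyte- and macrophage-like cells they numbered 969, and 615 with the per-cell marker score and 1923 with no filter. In mature neutrophil-like cells they numbered 715, and 318 with the per-cell score, 1189 with a replicate block and 1695 with no filter. Against 0 by edgeR, DESeq2 called 228 in B-cell-like, 149 in T-cell-like and 90 in erythroid-like cells. With no filter edgeR called 891 in T-cell-like and 440 in erythroid-like cells and 1315 for the interaction, and without genes of possible free RNA 6 in erythroid-like cells. The counts at an unadjusted p under 0.05 were 832, 839, 606 and, for the interaction, 2589. Over 471 named genes and the alternatives that keep all 4 libraries, 3837 of 4220 values kept their side of the threshold, 110 calls were lost and 273 gained, and with 1 library left out, over 470 of these genes, 1493 of 1873 kept it, 231 were lost and 149 gained. In both cases 0 calls changed direction. Camera's 85 list calls became 0 with an estimated correlation and 4 with fry. The cause was not tested.

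The share of precursor-like cells in the lineage turned its direction at Leiden resolution 0.5, from 1.05, not called, to -5.20, called (edgeR adjusted p = 0.0333). Cells so named then numbered 39, 0, 2 and 1 in WT replicates 1 and 2 and D3TA replicates 1 and 2, since all 291 cells of precursor-like cluster 33 joined immature cluster 8 there and only cluster 42 kept the name. The T-cell-like share, -0.40, was 0.40 with the per-cell score, 0.53 at resolution 0.5 and 0.21 with closest classes. The macrophage-like share, 0.31, was -0.28 with the stricter filter and -0.37 with the per-cell score, and the monocyte-like share, 0.70, was -0.19 with that score, all uncalled. The neutrophil-lineage share (log2) was 3.19 with unnamed clusters counted with their closest class. The immature share was 3.34 with the stricter filter, 3.70 with doublets kept, 3.12 with the per-cell score, 3.55 and 3.70 at Leiden resolutions 0.5 and 2 and 3.35 with closest classes, past the threshold in each. The mature share passed with the per-cell score (-1.91) and at resolutions 0.5 (-2.25) and 2 (-1.77).

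With WT replicate 1, WT replicate 2, D3TA replicate 1 or D3TA replicate 2 left out, where the lone mouse of a group is assumed to vary like the other group, the counts of genes were 333, 259, 1310 and 5423 in the whole spleen, 2074, 4849, 248 and 406 in neutrophil-like and 395, 662, 757 and 2239 in monocyte- and macrophage-like cells. They were 3, 0, 0 and 3012 in B-cell-like, 95, 416, 0 and 0 in T-cell-like and 0, 0, 0 and 2 in erythroid-like cells, 0, 479, 619 and 662 for the interaction and 81, 87, 81 and 90 for lists. Log2 shares ran from 2.34 to 3.72 for the neutrophil lineage, 2.52 to 6.51 for immature, -1.65 to -1.29 for mature and 0.49 to 2.86 for precursor-like cells. They ran from -3.33 to -0.66 for B, -0.94 to -0.01 for T, -5.29 to -0.93 for NK, 0.04 to 0.94 for erythroid, -0.24 to 0.71 for macrophage- and 0.23 to 1.19 for monocyte-like cells, and Ccnd3 from -0.27 to -0.07.

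Replicate numbers are not said to pair mice, and with 2 pairs cannot be shown to. The correlation of replicate differences was -0.08 in the whole spleen, -0.03 in neutrophil-like, -0.16 in monocyte- and macrophage-like, -0.19 in B-cell-like, -0.18 in T-cell-like and 0.11 in erythroid-like cells. With a replicate block, edgeR called 593 genes in monocyte- and macrophage-like and 99 in erythroid-like cells. A crossed block called 2018 genes in monocyte- and macrophage-like, 536 in B-cell-like and 263 in T-cell-like cells. The low depth per cell of WT replicate 1 and the 158 neutrophil-lineage cells of WT replicate 2 limit what was detectable in WT neutrophils.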

Other observations

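The tests of neutrophils per cell of other classes and of a shift of the whole library were chosen after the result was seen. In B-cell-like cluster 5, the most frequent highest heavy chain variable gene was Ighv5-6 in 62.3% of 130 cells (53.4 to 70.7, exact 95% interval) in D3TA replicate 1, and Ighv6-3 in 25.4% of 358 cells (20.99 to 30.3, exact 95% interval) in WT replicate 2. Cluster 20, with the germinal center genes Mybl1 and Rgs13 and the proliferation gene Mki67, held 1.71%, 1.55%, 0.739% and 0.843% of WT replicate 1, WT replicate 2, D3TA replicate 1 and D3TA replicate 2.

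The neutrophil-lineage share was higher in both D3TA than in both WT spleens, without passing edgeR (adjusted p = 0.0988). Averaged over the same bins of UMIs per cell, their shares were 4.11% and 3.34% in WT and 29.7% and 25.3% in D3TA replicates 1 and 2, a ratio of means of 7.37, which argues against low UMIs per cell in WT replicate 1 as the cause. Per macrophage-, monocyte-, dendritic cell-, erythroid- and plasma cell-like cell, the lowest D3TA number of such cells was at least 2.58 times the highest WT number under 8 settings of filter, doublets and naming, which argues against a loss of B cells alone. Per T-cell-like cell it was 4.82 times, but 1.15 times at Leiden resolution 0.5, where WT replicate 1 had 0.991 and D3TA replicate 2 1.14 such cells per T-cell-like cell, so T cells do not decide it. The genotype may go with more neutrophils, mostly immature, as a hypothesis, while the age of the mice, not tied to libraries by the labels, and yield during dissociation stay open and were not tested.

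Cell-cycle genes were higher in D3TA monocyte- and macrophage-like cells. If RNA or doublets of neutrophil precursors had brought them, granule genes would have come along, but the highest D3TA ratio of excess granule to excess G2/M UMIs was 1.78% of that in precursor-like cells. A different mix of clusters is argued against by monocyte-like cluster 25. There, with 42 and 55 WT cells, the lowest D3TA G2/M CPM was 7.67 times the highest WT one. More cycling monocyte-like cells in D3TA spleens is a candidate explanation. Cycling cells of another type lying within the main monocyte-like cluster were not tested.

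At least 90% of the cells of clusters 4, 9, 39 and 40 lay in D3TA replicate 1, 3611 cells or 30.7% of that library. Of its 5401 cells of named classes other than B and T cells, 0 lay in clusters above that limit at 3 Leiden resolutions. At most 0.685% lay in clusters whose interval reaches it. This test replaced earlier ones once cluster shares were seen and cannot decide on a whole-library shift. An earlier one gave 78.4%, 52.2% and 13.4% of those cells in clusters where D3TA replicate 2 had at least 0.5, 0.6 and 0.7 times its share. A shift of its lymphocytes stays open, since it held 0.0765% and 0.085% in T-cell-like clusters 16 and 19 and 1.44% in B-cell-like cluster 0, against at least 1.85%, 1.03% and 16.2% in the other libraries. Cluster 9, closest to B cells, had 12 of 13 B cell markers detected. It was left unnamed because its 10 leading genes held 1 marker of another class and 0 B cell markers. In cluster 9, Ighv1-52 was the highest heavy chain variable gene in 81.1% of the 185 cells with such a UMI, out of 1500. Growth of 1 B cell clone would give this. Such growth may be age-related or genotype-related, which 1 mouse cannot tell. Cluster 4, closest to T cells with 13 of 14 T cell markers detected, was left unnamed for the same reason. There Trbv14 led in 21.6% (17.8 to 25.9) of 416 cells. This was under the bound of 25% set beforehand for no clone but with an interval that includes it. The reading was first made from the value alone, which spoke against a clone, and the interval was required only after that value was seen, so growth of 1 T cell clone stays open; near-identical variable genes can also divide reads.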
